A study of Mus musculus with 12 samples.

How the data were processed

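RNA from 12 libraries of a mouse cell line, labelled MLO-Y4, was measured by sequencing after library preparation with a KAPA kit. The names of the deposited data carry the prefix MC3, which differs from this label, and the identity of the line was not tested. MLO-Y4 is an osteocyte-like line, and the plates were coated with type I collagen at 0.15 mg/mL. BIGH3 is the protein of the TGFBI gene, and recombinant human protein was added to the treated cells. Per the labels, the medium for differentiation held β-glycerophosphate at 4 mM, ascorbic acid at 50 µg/mL and serum at 10%. For undifferentiated cells the labels give none of these, so comparisons between the states cannot tell differentiation from a direct effect of the medium. The groups were undifferentiated control, undifferentiated BIGH3, differentiated control and differentiated BIGH3, with 3 libraries in each of the 4 groups. The BIGH3 dose, the time of treatment, what the controls received and the strand of the libraries were not given in the sources used here, so reads of overlapping genes on opposite strands were not told apart. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries.

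The submitters' processing notes name FastQC, cutadapt, Salmon, StringTie and the mm10 build, with versions that were not given in the sources used here. The deposited files, 1 per library, give for each transcript the estimated reads (expected counts that need not be whole, with shared reads divided between transcripts by the model). They also give TPM, a transcript share scaled to a fixed library sum and corrected for effective length by the authors, and the transcript length and effective length in bases, per the file headers. Of 147828 transcripts, 137063 (92.7%) were matched by identifier to the GENCODE M21 annotation of GRCm38 after the version suffix was dropped. The suffix was 1 version higher than in that annotation for 131373 of them, higher by more for 5653 and the same for 37. The unmatched transcripts held 1.28% to 3.67% of the reads of a library and were left out, since their identifiers are not in that annotation and their genes were not looked up. Estimated reads were summed per gene and rounded. The 51707 genes included 27964 with a read, and 67 symbols belonged to several gene identifiers, which were kept apart.

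Depth was 19014492 to 27612155 estimated reads per library. Genes were filtered with filterByExpr by group, which kept 14711 genes. Counts were scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood, robust, 1 term per group, 12 libraries together, 8 residual degrees of freedom). The biological coefficient of variation was 8.18% and the median standard error of a log2 fold change between 2 groups was 0.09. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a gene called at an adjusted p below 0.05. Comparisons were BIGH3 against control within each state, differentiated against undifferentiated within control and within BIGH3 treated cells, the interaction of both factors, and the BIGH3 effect averaged over both states. Errors are standard errors for fold changes and standard deviations for levels in CPM (counts scaled to library size), with n = 3 throughout. The standard errors were worked back from the test, as the size of the log2 fold change over the square root of its F statistic. For a gene with 1 to 3 reads in a group the ratio of rates is given with its 95% counting interval, and for a gene with 0 reads a bound is given against a floor of 3 reads over the group. Such intervals and floors cover counting error alone.

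The samples, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the named genes were the 10 largest rises and 10 largest falls among called genes (5 and 5 for differentiation in BIGH3 treated cells and for the interaction). They needed a mean log2 CPM of at least 2, a symbol that is not a predicted model and, outside the interaction, no overlap between the libraries of the groups. Gja1, the measured connexins and pannexins, Tgfbi, Bax and Bcl2 were always named, as were up to 4 members of each described list with the smallest adjusted p. Where fewer than 5 genes were called, the 5 with the smallest p under the same symbol and level rule were named. Some genes that met these rules are not reported here.

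The 36 lists covered connexins and pannexins, pro-apoptotic genes, anti-apoptotic genes, p53 targets, autophagy and lysosome genes, ER stress genes, amino acid response genes, NF-kB and inflammatory genes, interferon-stimulated genes, osteoblast genes, osteocyte markers, osteoclast regulators, mineralisation genes, TGF-beta targets, YAP and SRF targets and immediate early genes. They also covered integrins, matrix genes, matrix proteases, Wnt genes, G1/S genes, G2/M genes, senescence genes, cholesterol synthesis genes, hypoxia and glycolysis genes, NRF2 targets, heat shock genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes and ribosomal protein genes. Markers of adipocytes, chondrocytes, muscle, macrophages and osteoclasts, endothelium and epithelium completed them. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), and again with an estimated correlation. The fry test was run beside it, which asks whether a list's genes move on balance one way without comparing them with other genes. List p-values were adjusted over the 36 lists.

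Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals alone, no low-count filter, at least 1 CPM in 3 libraries, transcript length offsets, limma on log2(TPM + 1), a block for the replicate number, a fit to the 2 compared groups alone, an adjusted p below 0.01, a test against a change of 1.5-fold, and each library left out in turn. Runs without the 3 libraries that carried most liver transcripts, and without these and undifferentiated BIGH3 1, were added after seeing the data. The model was tested on simulated data at this size. Between 46 and 50 genes run were changed at each of 1.25-fold, 1.5-fold, 2-fold and 4-fold. With 14409 genes run in the undifferentiated design, 38.8% of genes changed 1.25-fold, 72.9% changed 1.5-fold and 95.8% changed 4-fold were recovered. Of unchanged genes 0.063% were called. In the differentiated design these shares were 39.1%, 58.3%, 89.8% and 0.050%. The adjusted p depends on how many genes change, so these shares need not hold for the real comparisons, which called 3 and 6687 genes. The replicate numbers did not pair the libraries, since 3 of 12 libraries had their closest partner under their own number, so no block was used in the fit reported. Other tools were R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.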

Results

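The transcriptome of cells labelled MLO-Y4, whose identity was not tested here, was measured in 12 libraries, 3 in each of 4 groups. Depth was 20545484 to 27612155 estimated reads per library in undifferentiated controls, 20999664 to 23927498 in undifferentiated BIGH3 treated cells, 22803778 to 25736952 in differentiated controls and 19014492 to 23560231 in differentiated BIGH3 treated cells. The first principal component of log2 CPM held 45.4% of the variance and separated differentiated from undifferentiated libraries. The second held 23.0% and separated treated from control libraries within the differentiated cells, while the undifferentiated libraries of both treatments lay mixed. Along the third, with 8.08%, undifferentiated control 2, differentiated BIGH3 3 and differentiated control 2 stood apart. These 3 libraries carried liver transcripts, with Afp, encoding the fetal plasma protein alpha-fetoprotein, at 63.3, 27.0 and 24.9 CPM. Undifferentiated BIGH3 1 carried them at a lower level, with Afp at 11.2 CPM against at most 3.64 CPM in the other 8, and lay on the same side of the third component.

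**Figure D1:**
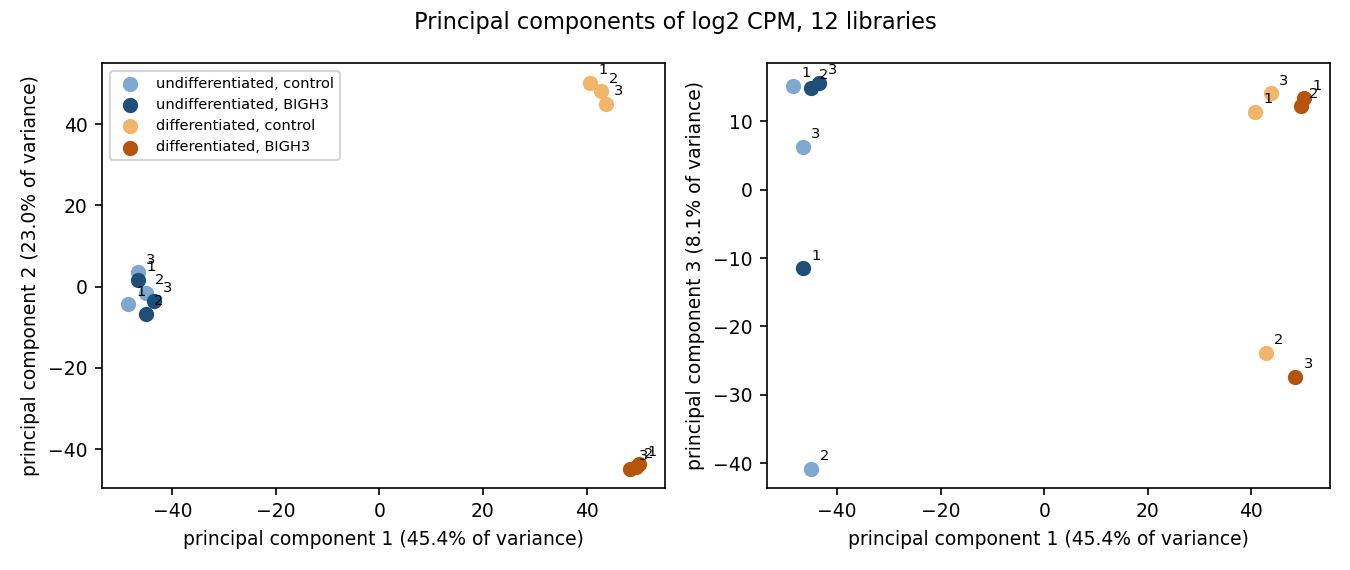
Each point is a library placed by its scores on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, coloured by group and numbered by replicate. Treated and control libraries lie apart along component 2 in differentiated cells and mixed in undifferentiated cells, and 3 libraries from 3 groups lie apart along component 3.

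The stated question of the series was the effect of BIGH3 on Gja1, which encodes the main gap junction protein of osteocytes (ENSMUSG00000050953.10, GRCm38 chromosome 10, 56377330 to 56402513). In undifferentiated cells Gja1 stood at 134 ± 1.7 CPM in controls and 139 ± 7.6 CPM with BIGH3 (SD, n = 3), a log2 fold change of 0.05 ± 0.05 (-0.03 in TPM) that was not called (adjusted p = 1.00). In differentiated cells it rose 1.74-fold with BIGH3, from 119 ± 3.6 to 207 ± 5.3 CPM, and each treated library (204 to 213 CPM) lay above each control (115 to 122 CPM). This log2 fold change of 0.80 ± 0.05 was called (adjusted p = 1.98e-11), and it exceeded that in undifferentiated cells by 0.75 ± 0.07 (interaction, adjusted p = 2.89e-08).

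Other channel genes fell with BIGH3 in differentiated cells. Panx3, a pannexin of bone and cartilage cells, fell by 2.32 on the log2 scale, from 24.4 ± 2.8 to 4.88 ± 0.36 CPM (adjusted p = 2.71e-13). The connexin gene Gjb5 fell by 1.92 on the log2 scale. Gjc1 and Gjb1 had log2 fold changes of 0.15 and -0.28 and were not called. Of 8 connexins and pannexins tested, 1 rose and 4 fell (5 adjusted over the list alone), and the list as a whole was not called against other genes (adjusted p = 0.189). In undifferentiated cells no member was called and their median log2 fold change was -0.02. Tgfbi, the mouse gene of the added protein, rose 1.72-fold in differentiated cells, from 83.8 ± 0.71 to 144 ± 8.3 CPM, and stood at 34.6 ± 1.6 and 34.7 ± 1.5 CPM without and with BIGH3 in undifferentiated cells.

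**Figure D2:**
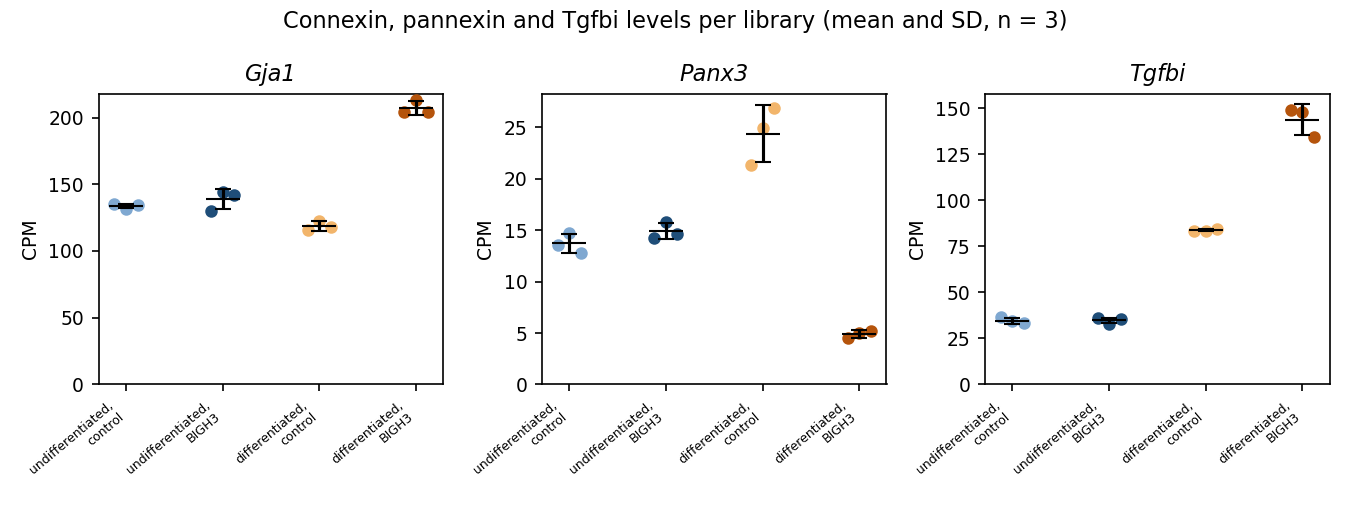
Levels of Gja1, Panx3 and Tgfbi in CPM (vertical axes from 0) in each library of the 4 groups, with points for libraries and bars for the mean and SD of 3. With BIGH3, Gja1 and Tgfbi lie higher and Panx3 lower in differentiated cells, and all 3 overlap their controls in undifferentiated cells.

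The 2 genes called lower with BIGH3 in undifferentiated cells were both of the immediate early class. Fosb, an AP-1 transcription factor, fell 2.28-fold from 40.7 ± 3.7 to 17.8 ± 4.3 CPM (log2 fold change -1.19 ± 0.15), and Egr1, a zinc finger transcription factor of the same class, fell 1.34-fold from 217 ± 17 to 161 ± 12 CPM (each with adjusted p = 0.0214). Zfp36, whose product destabilises inflammatory mRNAs, had a log2 fold change of -0.37 (adjusted p = 0.101), Fos one of -0.88 (adjusted p = 0.485) and Ramac, encoding a subunit of the mRNA cap methyltransferase, one of 0.29 (adjusted p = 0.211), and none of these was called. Fos was called without undifferentiated BIGH3 1 (adjusted p = 4.88e-06), without it and the 3 libraries with most liver transcripts (5.32e-06), with a replicate block (0.0310), by DESeq2 (0.0268) and without a low-count filter (6.28e-07). Zfp36 was called by DESeq2 (0.00230), with library totals (0.0476) and without that filter (6.70e-05), and Ramac by DESeq2 (0.0243) and without that filter (0.00954). The remaining call, 3110045C21Rik, an antisense transcript named after its values were seen, rose from 0.082 to 1.27 CPM (adjusted p = 0.0327). Its call ended with a replicate block (0.129), length offsets (0.391) and the compared groups alone (0.436), without any 1 of the undifferentiated BIGH3 libraries (0.0842, 0.192 and 0.159), and without undifferentiated control 1 (0.241) or 3 (0.191).

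Those 3 genes, 1 higher and 2 lower of 14711, were the whole count for undifferentiated cells by edgeR, with 599 genes at an unadjusted p below 0.05. The 599 made up a share of the genes tested below 0.05, the share that tests without any effect would give. DESeq2 called 8 genes, and the count was 1 without the 3 libraries with most liver transcripts, 5 without these and undifferentiated BIGH3 1, 0 without undifferentiated control 1 and 1 without undifferentiated control 2. The Fosb call ended without undifferentiated BIGH3 2 (adjusted p = 0.212), control 1 (0.241) or control 2 (0.133), without the 3 libraries with most liver transcripts (0.254), in TPM (0.0512) and with the compared groups alone (0.852). The Egr1 call ended without BIGH3 1 (0.0842), BIGH3 3 (0.172), control 1 (0.241) or control 2 (0.166), without the 3 (0.148) or 4 (0.176) libraries with liver transcripts, with length offsets (0.391), in TPM (0.181) and with the compared groups alone (0.125).

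Among the lists, 2 of 32 immediate early genes fell with BIGH3 in undifferentiated cells and none rose (7 adjusted over the list alone), and the list was lower than other genes (adjusted p = 4.22e-06). The call was lost, at adjusted p = 0.572 with an estimated correlation. Ribosomal protein genes (median log2 fold change 0.06, adjusted p = 3.42e-07), mitochondrially encoded genes (0.32, adjusted p = 9.56e-05) and G2/M genes (0.07, adjusted p = 0.00117) lay higher than other genes by the preset test, without a called member, and each had an adjusted p = 0.981 with an estimated correlation. The other 32 lists were not called and held 0 called members, over all genes and adjusted over the list alone. Those lists included pro-apoptotic genes (median log2 fold change -0.01) and NF-kB and inflammatory genes (median 0.00), and fry called 0 of the 36.

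Among the largest rises with BIGH3 in differentiated cells, Saa3, an acute-phase serum amyloid, rose 282-fold from 5.75 ± 2.6 to 1645 ± 188 CPM, Lcn2, which binds bacterial siderophores, 281-fold, and Cxcl5, a chemokine for neutrophils, 270-fold. C3, the central complement component, rose 21.8-fold to 5112 ± 204 CPM (adjusted p = 7.47e-23), and Hp, encoding the haemoglobin-binding haptoglobin, rose 94.8-fold to 1252 ± 33 CPM. Nos2, the inducible nitric oxide synthase, rose 109-fold, the metalloreductase gene Steap4 151-fold, the protease inhibitor genes Serpina3f and Serpina3g 75.3-fold and 41.0-fold, and Car9, a carbonic anhydrase, 24.6-fold.

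Among the largest falls, Cnmd, encoding the cartilage protein chondromodulin, fell by 6.78 ± 0.33 on the log2 scale and Cilp, encoding a cartilage matrix protein, fell by 5.49 ± 0.24, from 24.0 ± 0.22 to 0.528 ± 0.022 CPM. Apod, an apolipoprotein, fell 8.95-fold from 3602 ± 169 to 402 ± 7.0 CPM. Megf6 fell 24.0-fold, the integrin subunit gene Itga8 9.68-fold, Cyb561, of an ascorbate-dependent electron transporter, 9.29-fold, the cytokine-like gene Cytl1 9.15-fold and the synuclein gene Sncg 8.59-fold. Hist2h2aa2, a histone gene, had 0 reads in differentiated BIGH3 libraries and was at least 235-fold lower against a floor of 3 reads over the group. Its near-identical copy Hist2h2aa1 was expressed throughout, and Hist2h2aa2 also had 0 reads in undifferentiated BIGH3 2. Its call (adjusted p = 0.0343) ended without differentiated BIGH3 1 (0.0715), 2 (0.0686) or 3 (0.0668), and without differentiated control 1 (0.0760) or 3 (0.0750). It also ended without the 3 (0.112) or 4 (0.168) libraries with liver transcripts, without a low-count filter (0.0637), with a replicate block (0.0624) and with the compared groups alone (0.0674). Ints9, a subunit of the Integrator complex, fell by 5.84 ± 1.42, with 5, 7 and 4 reads in the treated libraries. Differentiated control 2 had 9 reads, near the treated level, against 581 and 503 in controls 1 and 3, so the fall rests on these 2 controls. The undifferentiated libraries had 578 to 636 reads.

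BIGH3 changed 6687 of 14711 genes in differentiated cells (45.5%), 3322 higher and 3365 lower, of which 1003 and 571 by over 2-fold. Without the 3 libraries with most liver transcripts the count was 5393, and without 4 it was 5399.

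NF-kB and inflammatory genes rose together with BIGH3 in differentiated cells: 33 of 37 tested rose and 1 fell (34 adjusted over the list alone). Their median log2 fold change was 1.44, and the examples besides C3 and Nos2 were Nfkbiz, an NF-kB cofactor (3.48), and Zc3h12a, an RNase that degrades cytokine mRNAs (2.18). The list was higher than other genes (adjusted p = 9.4e-21, and adjusted p = 0.0119 with an estimated correlation). Of 21 osteoclast regulators 13 rose and 3 fell (16 adjusted over the list alone, adjusted p = 0.000265). The prostaglandin synthase gene Ptgs2 (1.44) and the chemokine genes Ccl2 (2.75) and Cxcl12 (1.24) rose, and Tnfrsf11b, encoding the RANKL decoy osteoprotegerin, fell by 1.48 on the log2 scale to 107 ± 4.7 CPM. That list had an adjusted p = 0.0692 with an estimated correlation. Of 16 senescence genes 11 rose and 2 fell (13 adjusted over the list alone, adjusted p = 0.000326, and adjusted p = 0.235 with an estimated correlation). The insulin-like growth factor binding protein gene Igfbp5 fell by 1.08.

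Proliferation and sterol genes rose as well. All 35 G1/S genes rose (35 adjusted over the list alone), with a median log2 fold change of 1.27 and the helicase genes Mcm3 (1.64), Mcm5 (2.15) and Mcm2 (1.58) as examples (adjusted p = 2.61e-21, and adjusted p = 0.0242 with an estimated correlation). All 35 G2/M genes rose (35 adjusted over the list alone), with a median of 2.15 and the centromere genes Cenpf (2.44) and Cenpe (2.01) and the topoisomerase gene Top2a (2.01) as examples. The G2/M list had an adjusted p = 6.46e-29, and an adjusted p = 0.0692 with an estimated correlation. Of 24 cholesterol synthesis genes 18 rose and none fell (19 adjusted over the list alone), among them the enzyme genes Msmo1 (0.91), Fdft1 (0.80) and Sqle (0.73). Their list was called with both correlations (adjusted p = 4.43e-08, and adjusted p = 0.0189 with an estimated correlation).

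Of 30 osteoblast genes 20 fell and 4 rose (25 adjusted over the list alone, adjusted p = 0.000873, and adjusted p = 0.0245 with an estimated correlation). Kazald1 and Omd, genes of matrix proteins of bone, fell by 2.00 and 1.74 on the log2 scale. Spp1, encoding osteopontin, rose by 1.72, from 3211 ± 98 to 10599 ± 460 CPM, and the collagenase gene Mmp13 rose by 1.84. Among 12 osteocyte markers 4 rose and 4 fell (8 adjusted over the list alone), and the list was not called (adjusted p = 0.997). Dmp1, of a mineralising matrix protein, rose from 37.1 ± 1.5 to 85.7 ± 8.3 CPM, and Phex, an endopeptidase of phosphate control, fell from 83.8 ± 3.6 to 23.9 ± 2.6 CPM. Sost, encoding the Wnt inhibitor sclerostin, had 10 reads over the differentiated controls and 0 in each other group, the phosphate hormone gene Fgf23 had 0 in all 4 groups, and Tnfsf11, encoding the osteoclast factor RANKL, had 9 over the differentiated BIGH3 libraries and 0 elsewhere. Of 15 mineralisation genes 8 rose and 6 fell (14 adjusted over the list alone, adjusted p = 0.309).

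Apoptosis genes moved both ways with BIGH3 in differentiated cells. Of 28 pro-apoptotic genes 7 rose and 9 fell (16 adjusted over the list alone, adjusted p = 0.929), with the death receptor gene Fas 2.76 and Trp53, encoding p53, 0.44 higher on the log2 scale. The initiator caspase gene Casp9 fell by 0.61. Bax, a pore-forming death effector, fell by 0.18 ± 0.06 (adjusted p = 0.0213), a call that ended in TPM (0.160) and without differentiated BIGH3 1 (0.106) or control 1 (0.0799). Of 11 anti-apoptotic genes 6 rose and 2 fell (8 adjusted over the list alone, adjusted p = 0.0836), with Bcl2 0.89, Birc3 1.40, Cflar 0.52 and Birc5, which also acts in mitosis, 2.17 higher. Of 27 p53 targets 8 rose and 8 fell (16 adjusted over the list alone, adjusted p = 0.557).

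Other lists fell on balance by the preset test in differentiated cells and lost the call with an estimated correlation. Of 17 heat shock genes 10 fell and 0 rose (10 adjusted over the list alone, adjusted p = 0.00322, and adjusted p = 0.404 with an estimated correlation), among them the small chaperone gene Cryab (-0.95). Of 40 nuclear oxidative phosphorylation genes 17 fell and 1 rose (18 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.712 with an estimated correlation). Of 47 ribosomal protein genes 16 fell and 0 rose (14 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.739 with an estimated correlation). Chondrocyte markers fell in 7 of 9 (7 adjusted over the list alone, adjusted p = 0.00322), among them the cartilage collagen gene Col2a1 (-2.91), with an adjusted p = 0.0777 with an estimated correlation. Muscle markers fell in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.0129), among them the troponin gene Tnnt3 (-1.81), with an adjusted p = 0.122 with an estimated correlation.

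The remaining lists were not called for BIGH3 in differentiated cells, although many members were. Rises and falls were 13 and 14 of 50 autophagy and lysosome genes, 5 and 7 of 25 ER stress genes, 7 and 6 of 28 amino acid response genes, 13 and 16 of 51 interferon-stimulated genes and 14 and 9 of 32 TGF-beta targets. Adjusted over the list alone, 27, 12, 13, 31 and 23 members of these were called. They were 7 and 12 of 26 YAP and SRF targets, 11 and 7 of 32 immediate early genes, 2 and 6 of 18 integrins, 15 and 26 of 54 matrix genes, 14 and 12 of 33 matrix proteases and 4 and 6 of 15 Wnt genes. Adjusted over the list alone, 19, 19, 8, 41, 26 and 10 of these were called. Of 30 hypoxia and glycolysis genes 10 rose and 8 fell, of 24 NRF2 targets 3 rose and 13 fell, and of 15 mitochondrially encoded genes 0 rose and 1 fell, with 18, 20 and 1 called when adjusted over the list alone. Among markers of other cell types, 3 of 5 adipocyte, 2 of 6 macrophage and osteoclast, 1 of 4 endothelial and 0 of 4 epithelial genes rose. Of the same markers 1, 1, 1 and 2 fell, and 4, 3, 3 and 2 were called when adjusted over the list alone. Camera called 12 of 36 lists, 4 of them also with an estimated correlation, and fry called 26. Mean and median had opposite signs for mineralisation genes (-0.09 and 0.29), immediate early genes (0.06 and -0.06), mitochondrially encoded genes (-0.09 and 0.05), adipocyte markers (-0.44 and 0.26), autophagy and lysosome genes (-0.02 and 0.01) and interferon-stimulated genes (0.04 and -0.02).

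**Figure D3:**
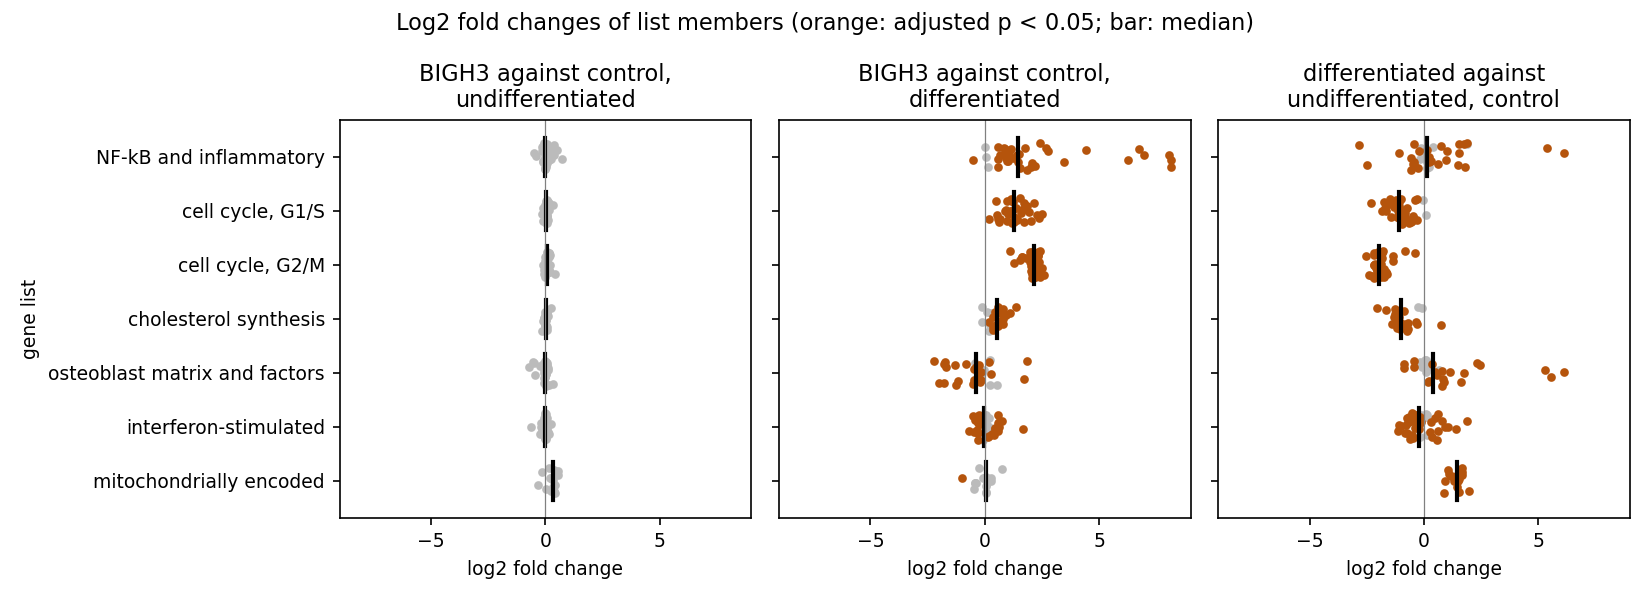
Log2 fold changes of the members of 7 gene lists in 3 comparisons; each point is a gene, orange where called, and the black bar is the list's median. With BIGH3 the NF-kB, cell cycle and cholesterol synthesis lists lie right of 0 in differentiated cells and near 0 in undifferentiated cells, and differentiation of control cells moved the cell cycle and cholesterol synthesis lists to the left.

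Among the largest rises on differentiation of control cells, Lum, a collagen-binding proteoglycan gene, rose 87.1-fold from 2.96 ± 0.35 to 260 ± 12 CPM, and Cilp rose 212-fold. F13a1, the subunit of a fibrin-crosslinking enzyme, rose 99.7-fold, the dipeptidase gene Dpep1 92.2-fold, Clec3b, encoding tetranectin, 80.5-fold, the chemokine scavenger gene Ackr4 70.6-fold and Sncg 69.5-fold. Agr2, a disulfide isomerase gene, had 3 reads in undifferentiated controls and a ratio of 708 (242 to 3437), Angptl1 had 2 reads and a ratio of 554 (153 to 4582), and the kininogen gene Kng2 had 2 reads and a ratio of 94.1 (25.7 to 783). Fos fell 31.0-fold, Egr1 7.34-fold and Zfp36 5.72-fold. The mitotic phosphatase gene Cdc25c fell 5.76-fold, the spindle gene Troap 6.06-fold, the DNA helicase gene Pif1 6.09-fold, the corepressor gene Tle2 6.10-fold, the collagen gene Col28a1 9.82-fold, the nuclease gene Ankle1 11.1-fold and Car9 12.6-fold.

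Gja1 fell by 0.17 ± 0.05 on the log2 scale (adjusted p = 0.00478), and by 0.32 when scaled by library totals. Gjc1 fell by 0.51, Panx3 rose by 0.83 and Tgfbi by 1.28, while Gjb5 (-0.07) and Gjb1 (-0.39) were not called. In all 1 of 8 connexins and pannexins rose and 4 fell (5 adjusted over the list alone, adjusted p = 0.257). Bcl2 fell by 0.29 (adjusted p = 0.0162), a call that ended with length offsets (0.0983) and without undifferentiated control 1 (0.0616) or differentiated control 1 (0.115). Bax stood at 0.03 and was not called, but it was called lower in TPM, at -0.26 (adjusted p = 0.00516).

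Between the control states 8491 genes changed (57.7%), 4287 higher and 4204 lower. With library totals the median log2 fold change of all genes was -0.16, against -0.01 with TMM, and 2930 genes were higher and 5899 lower. TPM gave 1728 higher and 6965 lower, so directions of small changes are relative to the scaling.

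All 35 G2/M genes fell on differentiation in control cells (35 adjusted over the list alone, adjusted p = 3e-21), with a median log2 fold change of -1.94 and the genes Hmmr (-2.11) and Anln (-2.15) of the spindle and the cleavage furrow as examples. Of 35 G1/S genes 33 fell and 0 rose (33 adjusted over the list alone, adjusted p = 8.38e-13). The estimated correlation ended both calls, at adjusted p = 0.0861 and adjusted p = 0.0598 with an estimated correlation. Of 24 cholesterol synthesis genes 20 fell and 1 rose (22 adjusted over the list alone), among them Sqle (-1.31). That list kept its call (adjusted p = 7.13e-10, and adjusted p = 0.0184 with an estimated correlation). Of 27 p53 targets 19 fell and 3 rose (22 adjusted over the list alone, adjusted p = 0.000498, and adjusted p = 0.0437 with an estimated correlation). The members with the smallest p among these were Ckap2 (-2.15) and Gtse1 (-1.73), genes of spindle proteins, and Trp53inp1 (-0.90).

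Of 30 osteoblast genes 17 rose and 4 fell on differentiation (22 adjusted over the list alone, adjusted p = 0.00201, and adjusted p = 0.0437 with an estimated correlation). Among them were Mmp13 (6.12), the osteocalcin gene Bglap2 (2.34), the matrix gene Postn (1.61) and Spp1 (0.87). Of 24 NRF2 targets 15 rose and 2 fell (19 adjusted over the list alone, adjusted p = 0.00040, and adjusted p = 0.0437 with an estimated correlation), with the quinone reductase gene Nqo1 (1.62) as an example. All 15 mitochondrially encoded genes rose (15 adjusted over the list alone, median log2 fold change 1.45, adjusted p = 1.56e-05), with an adjusted p = 0.290 with an estimated correlation. Their genome took 3.91% to 5.72% of reads in undifferentiated and 7.72% to 11.1% in differentiated libraries. Of 40 nuclear oxidative phosphorylation genes 27 rose and 1 fell (29 adjusted over the list alone, adjusted p = 0.000141, and adjusted p = 0.403 with an estimated correlation).

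Further lists were called on differentiation by the preset test alone. Of 50 autophagy and lysosome genes 32 rose and 4 fell (37 adjusted over the list alone, adjusted p = 8.28e-05, and adjusted p = 0.0861 with an estimated correlation). Of 25 ER stress genes 19 rose and 1 fell (20 adjusted over the list alone, adjusted p = 3.97e-05, and adjusted p = 0.178 with an estimated correlation). Of 33 matrix proteases 19 rose and 7 fell (28 adjusted over the list alone, adjusted p = 0.00135, and adjusted p = 0.0598 with an estimated correlation), with the cathepsin gene Ctsk 3.53 higher. Of 15 mineralisation genes 9 rose and 4 fell, with Phex 3.35 higher (13 adjusted over the list alone, adjusted p = 0.0232, and adjusted p = 0.0861 with an estimated correlation). Muscle markers rose in 8 of 10 and fell in 1 (9 adjusted over the list alone, adjusted p = 0.0030, and adjusted p = 0.074 with an estimated correlation). Of 28 amino acid response genes 16 rose and 6 fell (22 adjusted over the list alone, adjusted p = 0.0332, and adjusted p = 0.290 with an estimated correlation). Of 32 immediate early genes 17 fell and 4 rose (21 adjusted over the list alone, adjusted p = 0.00495, and adjusted p = 0.290 with an estimated correlation). Of 51 interferon-stimulated genes 28 fell and 12 rose (41 adjusted over the list alone, adjusted p = 0.0456, and adjusted p = 0.693 with an estimated correlation).

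Library totals gave fewer rises and more falls for several lists that rose: 24 and 15 for autophagy and lysosome genes, 14 and 3 for nuclear oxidative phosphorylation genes, 14 and 2 for ER stress genes, 15 and 7 for osteoblast genes, 13 and 3 for NRF2 targets, 18 and 10 for matrix proteases and 14 and 8 for amino acid response genes.

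The other 20 lists were not called on differentiation, 16 lists being called by camera, 4 of them also with an estimated correlation, and 33 by fry. NF-kB and inflammatory genes rose in 16 and fell in 11 of 37 (28 adjusted over the list alone), a balance that library totals turned to 13 and 14. The balance of anti-apoptotic genes (5 higher, 4 lower), osteoclast regulators (8 and 7) and TGF-beta targets (13 and 12) also turned with library totals. Of 54 matrix genes 26 rose and 14 fell (41 adjusted over the list alone, adjusted p = 0.0587), against 21 and 20 with library totals. Mean and median had opposite signs for TGF-beta targets (0.24 and -0.05), and both lay below 0 for anti-apoptotic genes (-0.03 and -0.08), which the test placed above other genes.

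Differentiation of BIGH3 treated cells changed 8329 genes, 4253 higher and 4076 lower, against 3107 and 5304 with library totals and 2119 and 5770 in TPM. Saa3, Nos2, Hp and Mmp13 rose 579-fold, 333-fold, 296-fold and 250-fold, and Steap4, with 2 reads in undifferentiated treated cells, had a ratio of 1845 (510 to 15241). Fos fell 27.2-fold, Cnmd 24.3-fold and the cadherin-related gene Cdhr1 23.9-fold, Col2a1 fell 17.0-fold from 112 ± 14 to 6.66 ± 0.96 CPM, and Ints9 fell by 6.57 ± 1.35 on the log2 scale. Gja1 rose by 0.58 ± 0.05 (adjusted p = 2.49e-09) and Tgfbi by 2.05, while Gjb5, Panx3 and Gjc1 fell by 1.88, 1.61 and 0.36. Gjb1 (1.06) was not called. Bax fell by 0.23 and Bcl2 rose by 0.40, against 0.14 in TPM, where it was not called (adjusted p = 0.242). For lists, camera called 18 of 36 in treated cells, 12 higher and 6 lower, 2 of them also with an estimated correlation, and fry called 31. The 2 were NF-kB and inflammatory genes, with 35 of 37 higher and 1 lower (37 adjusted over the list alone, adjusted p = 2.8e-18, and adjusted p = 0.0168 with an estimated correlation), and mineralisation genes, with 12 of 15 higher and 1 lower (14 adjusted over the list alone, adjusted p = 6.58e-05, and adjusted p = 0.0228 with an estimated correlation). Of 35 G1/S genes 19 rose and 2 fell (21 adjusted over the list alone, adjusted p = 0.00235, and adjusted p = 0.312 with an estimated correlation). Across the states 5877 genes were called both in control and in treated cells, 88.6% of them in the same direction, with 2710 higher in both (1239 if independent) and 2497 lower in both (1165 if independent).

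The BIGH3 effect itself differed between the states for 4730 genes, 2378 with a higher and 2352 with a lower response in differentiated cells, and 2604 and 1981 with library totals. Among called genes with a mean log2 CPM of at least 2 and a symbol that is not a predicted model, Lcn2 (7.76), Cxcl5 (7.59), Saa3 (7.41), Nos2 (6.88) and Hp (6.45) had the largest log2 differences upward and Cnmd (-6.59), Cilp (-6.00), Ints9 (-5.92), Megf6 (-4.77) and Itga8 (-3.39) downward. The Ints9 call (adjusted p = 0.0274) ended in TPM (0.159), with a replicate block (0.0565) and without undifferentiated BIGH3 3, any undifferentiated control, any differentiated BIGH3 library, or differentiated control 1 or 3. The adjusted p-values without these libraries, each left out alone, ran from 0.0510 to 0.0734. In TPM the counts were 2214 and 1135. Panx3 (-2.44), Gjb5 (-1.81), Tgfbi (0.77), Bcl2 (0.69) and Bax (-0.26) also had called differences. Averaged over both states, BIGH3 changed 4454 genes, 2236 higher and 2218 lower. With 3 genes called in undifferentiated and 6687 in differentiated cells, this average does not mark changes shared by both states.

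Of the 4614 genes called both for differentiation in controls and for BIGH3 in differentiated cells, 74.7% moved in opposite directions. There were 1743 up then down (981 if independent) and 1704 down then up (949 if independent). Another 605 rose in both (968 if independent) and 562 fell in both (962 if independent). Both comparisons share the differentiated controls, which alone gave a correlation of -0.50 across genes in simulated data without any effect, against -0.38 here. The simulated covariance was -0.0981 against -0.36 here, and the 20 simulations had a mean of 0.15 genes called in both. Since no effect was simulated, these runs cannot tell how much of the 74.7% comes from the shared controls.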

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

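The test of the spread between libraries was chosen only after the result was seen, and the other tests given here were planned. The effect of BIGH3 differed between differentiated and undifferentiated cells by the test of the difference itself for 4730 genes, and for Gja1 by 0.75 ± 0.07 on the log2 scale. Of the 20 genes named for BIGH3 in differentiated cells, 18 had a called difference, while those of Steap4 (adjusted p = 0.294) and Hist2h2aa2 (adjusted p = 0.0948) were not called. The 20 were picked by their change in differentiated cells, which enters this difference, so the count of 18 adds no support. Steap4 had 2 reads in undifferentiated BIGH3 libraries, and its difference was 6.40 ± 4.25. The difference was also called, with the preset and with an estimated correlation, for 6 lists. The adjusted p-values with an estimated correlation were 0.00811 for NF-kB and inflammatory genes, 0.0209 for G1/S and for cholesterol synthesis genes, 0.0257 for osteoblast genes, and 0.0440 for G2/M genes and for osteoclast regulators.

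Technical explanations were weighed for the near absence of a response in undifferentiated cells. The median standard error there was 1.02 times that in differentiated cells, each from its own 6 libraries, which argues against a wider spread. Over the 6687 genes called in differentiated cells, the slope of the undifferentiated on the differentiated log2 fold changes was 0.00686, against up to 0.0305 in size for the 9 other splits, which argues against the same response at a smaller size. The slope of a single undifferentiated library on that response reached -0.0317 at most in size, which argues against an exchange of libraries that carried the differentiated response. An exchange among libraries with another response, or with none, would not show in these slopes. A difference between the states in how the cells respond may remain as a hypothesis, found and tested on the same data, and whether both states received the same dose for the same time was not tested.

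Other groupings of the same libraries were counted for each comparison. For the difference between the states 5 of 100 splits within the states gave as many genes, with 5416 as the highest other count against 4730. For the average over both states 6 of 100 did, with 5048 against 4454. The 6 other splits that kept the real differentiated groups gave 4577 to 5416 genes for the difference and 4407 to 5048 for the average. Such splits keep the response of the differentiated cells, so these shares cannot decide about chance. All of the other splits that gave as many, 4 and 5, kept the real differentiated groups and regrouped the undifferentiated libraries alone, and the 93 splits that regrouped the differentiated libraries gave 0 genes in either case. The 10 splits of 3 against 3 are too few for a share under 0.05. The real count and the highest other were 6687 and 1 for BIGH3 in differentiated cells, 3 and 7 in undifferentiated cells, 8491 and 1 for differentiation in controls, and 8329 and 1 in treated cells. For lists they were 12 and 10, 4 and 6, and 16 and 11 in the first 3 of these comparisons. Every other split put libraries of both groups on each side, so a real effect would stay in part and widen the spread. The other counts are therefore not a level given by chance alone.

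Reads outside the gene counts reached 2.90% of a library on a single transcript, ENSMUST00000240377.1, whose identifier is not in the annotation used. Its share averaged 0.612% in undifferentiated controls, 0.562% in undifferentiated BIGH3, 2.09% in differentiated controls and 2.27% in differentiated BIGH3 libraries.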

How the results depend on the processing

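The tests without the 3 or 4 libraries with liver transcripts, and those of Gja1 at an adjusted p below 0.01 and against 1.5-fold, were chosen only after seeing the data. BIGH3 in undifferentiated cells rested on few genes: against 3 called, DESeq2 called 8, no low-count filter 21, length offsets 1, limma on TPM 1, the 2 compared groups alone 0, an adjusted p below 0.01 0, a change of over 1.5-fold 0, the run without the 3 libraries with liver transcripts 1 and that without 4 libraries 5. Leaving out single libraries gave 0 to 3, with 0 without undifferentiated control 1 and 1 without undifferentiated control 2. Its 4 lists became 0 with an estimated correlation, 0 by fry, and 2 to 7 without single libraries, with 7 without control 1 and 2 without control 3. For differentiated cells the lists went from 12 to 4 with an estimated correlation and 26 by fry, and for differentiation in controls from 16 to 4 and 33, with 10 to 12 and 16 to 18 without single libraries. A test against 1.5-fold, which asks for a larger change, gave 1446 genes for BIGH3 in differentiated cells, 2200 for differentiation in controls, 1898 in treated cells, 1017 for the interaction and 394 for the average, and the interaction had 3066 at an adjusted p below 0.01. Single libraries left out gave 5896 to 6138, 7824 to 8103, 7498 to 7941, 4051 to 4693 and 3980 to 4291 genes in the same order. A block for the replicate number gave 3, 6639, 8442, 8299, 4669 and 4422 genes and left the lists at 4, 12 and 16. The other alternatives left these 5 counts within 1.5 times, with 5145 genes for BIGH3 in differentiated cells by limma on TPM. Gja1 in differentiated cells was called in every alternative, at log2 fold changes of 0.77 to 0.84 (adjusted p = 0.000344 against 1.5-fold), and in undifferentiated cells in none, at -0.03 in TPM and 0.02 to 0.10 elsewhere. Over 227 results for single genes, 3822 values kept their call or lack of one, 54 lost the call, 16 gained one and 1 turned. The last was Bax on differentiation of controls, at -0.26 by limma on TPM. Directions were compared only where a gene was called in either setting. The adjusted p below 0.01 and the test against 1.5-fold were not applied to these results. Apart from the stricter thresholds, the cause was not tested. Depth limited genes with few reads, such as Gjb1, Sost and Tnfsf11.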

Other observations

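The tests on receptors, imprinted genes, liver transcripts, leukocyte genes and the bacterial product were all chosen only after the results were seen, with lists written for them. Receptors and adaptors for bacterial products and inflammatory cytokines rose with BIGH3 in differentiated cells in 15 of 24 and fell in 3 (adjusted p = 6.67e-05 over 4 such lists, and adjusted p = 0.0256 with an estimated correlation). The leukemia inhibitory factor receptor gene Lifr rose by 2.07 on the log2 scale, from 209 to 876 CPM, the oncostatin M receptor gene Osmr by 1.84, the endotoxin co-receptor gene Cd14 by 1.93, the toll-like receptor genes Tlr2 by 1.80 and Tlr4 by 1.19, and the TNF receptor gene Tnfrsf1b by 1.58. In undifferentiated cells 0 of the 24 were called, and the difference between the states was called for the list (adjusted p = 5.00e-06, and adjusted p = 0.0133 with an estimated correlation).

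Igf2, a growth factor gene, and its imprinted neighbour H19 both fell with BIGH3 in differentiated cells, Igf2 by 2.71 ± 0.06 on the log2 scale from 1081 ± 60 to 165 ± 9.4 CPM and H19 by 2.58 ± 0.14 from 116 ± 6.7 to 19.3 ± 3.0 CPM. Differentiation of controls had raised Igf2 by 3.29 and left H19 at -0.01, not called. Of 10 imprinted growth genes tested 5 fell and 2 rose with BIGH3, and the list was not called (adjusted p = 0.0749).

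Liver transcripts stood out in undifferentiated control 2, differentiated BIGH3 3 and differentiated control 2, and at a lower level in undifferentiated BIGH3 1 (Afp 11.2, Ttr 4.50 and Rbp4 2.15 CPM, against at most 3.64, 1.36 and 0.374 in the other 8). In the first 3 of these libraries Alb, the main transcript of adult hepatocytes, reached 0.00581 of the Afp level at most, which argues against adult hepatocytes. Undifferentiated BIGH3 1 had Alb at 0.122 CPM against Afp at 11.2 CPM. Afp in the lowest of the 3 was 6.86 times that in the highest other library of their groups, which argues against an effect of the study groups. RNA or reads from another liver type of cell may remain: 28 of 54 hepatocyte genes with 10 or more reads were higher in each of the 3 libraries than in each of the other 9, but the 3 were picked by such transcripts, so this count tests nothing.

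The rise of NF-kB and inflammatory genes with BIGH3 in differentiated cells was weighed against other sources. Of 15 leukocyte genes 3 lay at 1 CPM or more in the treated libraries and were called higher. Fcer1g, 1 of these, rose from 0.144 to 1.45 CPM. Ptprc, the common leukocyte antigen gene, stood at 0.457 CPM in differentiated controls and 0.403 CPM in treated libraries. Of 7 such genes tested 0 were called lower, and camera did not call the list (adjusted p = 0.0749). The limit of 3 for arguing against leukocytes was set after the values were seen, and the count lay on it. A low level of leukocytes therefore cannot be excluded. A bacterial product in the protein preparation could give the same rise and cannot be told apart from the protein, since Tlr4 stood at 76.1 CPM in differentiated controls, and what the controls received is not given in the sources used here. Undifferentiated controls carried Tlr4 at 72.4 CPM, and with the protein 0 of 37 of these genes were called.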
